A study of Mus musculus with 39 samples.

How the data were processed

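Polyadenylated RNA of 39 mouse samples was measured by sequencing, in 13 groups of 3 libraries each. The groups are sorted granulocytic, monocytic and combined cells, and all cells, of newborn marrow, of the spleens of 2 kinds of mice and of intestine, and each sample was grouped by its label. Per the labels' protocols, cells were sorted into Trizol, libraries were made with the TruSeq stranded mRNA kit, and single reads of 75 bp were sequenced on an Illumina NextSeq. Per the submitters' processing notes, reads were written out with bcl2fastq 2.18, aligned to mm10 with STAR 2.6.1c and quantified per gene with RSEM. The version of RSEM and the annotation are not given in the sources used here. The deposited table holds gene-level TPM from RSEM, transcript shares scaled to a fixed total, for 53465 genes.

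Every library in the table sums to 1000000 TPM. TPM does not keep read counts, which were not used here, so the depth per sample is unknown, and no counting error or detection limit is given. A value of 0 is written as listed at 0. As deposited, 26 gene symbols had been turned into dates, and these were restored from their gene identifiers. Of the 53465 identifiers, 53274 were matched to gene names, and 220 entries with a repeated symbol were kept apart by identifier. No pair of libraries was identical. Genes with a TPM of at least 1 in at least 3 libraries (18466 of the 35653 above 0 in any library) were analysed as log2(TPM + 1).

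Differences were tested with limma 3.58.1 in R 4.3.3, with 1 mean per group fitted over all 39 libraries, a trend of variance with level, and two-sided moderated t tests (26 residual degrees of freedom, median prior 3.02). P values were adjusted by Benjamini and Hochberg over the 18466 genes of a comparison. A gene was called at an adjusted p under 0.05 with a log2 fold change of at least 1 in size. The 16 comparisons were granulocytic against monocytic sorts at 4 sites, intestine against spleen for 3 sorts, the 2 kinds of spleen for 3 sorts, spleen against marrow for 2 sorts, sorts against all cells for 3, and the difference of the granulocytic against monocytic contrast between intestine and spleen. Combined sorts were tested against each single sort. They were also placed between the mean profiles of the single sorts by least squares on TPM of the genes called between these, without genes over a TPM of 1000, with a share bounded at 0 and 1. The labels do not say whether the 3 libraries of a group come from separate animals, so the p values measure only the spread between samples. Means, sums and correlations were computed in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1.

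The 26 gene lists, all shown in the heatmap of the report, hold 396 genes, of which 395 are in the table. They were tested against all other genes with camera of limma, which compares mean moderated statistics, at its preset correlation of 0.01. The p values were adjusted over 416 tests, and the tests were repeated with the correlation estimated from the data. Genes called within a list were also counted with the adjustment taken over the list alone. Libraries were rescaled by their median ratio over the 6908 genes with a TPM of at least 5 in every library, as an alternative to TPM as deposited.

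The groups, the comparisons, the lists, the thresholds, the alternatives listed below and the rule for naming genes were set before the data were examined. The rule takes a fixed panel of 15 genes, the 6 largest and 6 smallest log2 fold changes among called genes without overlap between libraries and with a higher mean TPM of at least 20, up to 4 members at a TPM of at least 5 of each list that passed or is described, and 3 genes above and 3 below for the combined sorts. Symbols of provisional genes, immunoglobulin and T cell receptor segments and pseudogenes were left out of the largest and smallest. The genes in the text are a subset of those that the rule gives, chosen after their values were seen.

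Replicate numbers were checked for pairing by correlating, for each of 27 pairs of groups, the deviations of equally numbered libraries from their group means. The correlations passed 0.1 for each number in 5 of these. Among the comparisons made, the numbers pair the samples for G against M in APCmin/+ spleen (0.555, 0.375 and 0.404) and in intestine (0.599, 0.432 and 0.562), hence in the interaction, and for combined against all intestinal cells (0.643, 0.59 and 0.628). They also do for combined against G sorts in intestine (0.189, 0.137 and 0.184) and in APCmin/+ spleen (0.112, 0.33 and 0.2), although the combined and G libraries numbered 1 and 2 differ in sex-linked transcripts. This pairing comes from the data, since the labels do not say what a number marks. The alternatives tried were a pseudocount of 0.1, no filter, rescaling, no fold minimum, a fit of only the groups compared, replicate number as a block, each library left out in turn, and, for the position of combined sorts, no upper TPM limit and an error on the log2 scale. Where leaving out a library left 2 in a group, the spread came from all groups. Alternatives added later are named in the closing section. Each count was compared with those from other splits of its samples. The tests were run on simulated data with 200 changed genes in 4 of the comparisons. At a log2 change of 1.5 the calls recovered between 85% and 96% of the changed genes, at 3 between 95% and 100%, with between 2 and 5 unchanged genes called and 0 unchanged lists. The simulated noise was independent between genes and samples, with the same spread in every group. These rates therefore do not cover correlated genes, groups of unequal spread or paired samples. No library was left out of the results.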

Results

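RNA was sequenced from 39 mouse samples in 13 groups of 3 libraries. The series is about myeloid-derived suppressor cells, immature myeloid cells that restrain T cells and that the field divides into granulocytic (G) and monocytic (M) subsets. C57BL/6 mice, labelled newborn P7, gave single cells of bone marrow and its G and M sorts. Spleens of BALB/c mice labelled immune-deficient gave G sorts, M sorts and combined (G+M) sorts. Spleens of APCmin/+ mice, whose mutant Apc allele leads to intestinal tumours, gave the same 3 sorts, and intestines of APCmin/+ mice gave these 3 sorts and single cells of the tissue. The surface markers of the sorts and the stretch of intestine sampled are not given in the sources used here.

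The deposited values are TPM, transcript shares scaled to sum to 1000000 in every library, so the depth behind a value is unknown and no counting interval is given. Between 21551 and 24910 genes had a TPM above 0 in a library. Pearson correlations of log2(TPM + 1) across genes were between 0.9643 and 0.9926 within groups, and the highest between groups was 0.9885. In 25 of the 39 libraries the nearest other library belonged to the same group. The first principal component held 60.6% of the variance and the second 19.0%. The share of TPM from mitochondrial genes ran from 2.07% to 20.0%. It was 9.47% ± 0.216 in the BALB/c splenic G sort against 3.79% ± 0.206 in the M sort, 8.58% ± 0.322 against 4.40% ± 0.955 in APCmin/+ spleen, 16.1% ± 3.56 against 10.5% ± 3.29 in intestine, and 2.72% ± 0.134 against 2.16% ± 0.0768 in marrow. Levels below are mean TPM ± SD over 3 libraries, and log2 fold changes are given ± their standard error. Except where stated, the 3 libraries of the higher group all lay above the 3 of the other for each gene called in a comparison and given with its levels, which happens in a share of 0.1 of unchanged genes.

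Markers of other cell types were present in most sorted groups. The 23 intestinal epithelial genes fixed in advance summed to 31205 ± 2815 TPM in the intestinal G sort, 28602 ± 2855 in the M sort and 25117 ± 3772 in the combined sort, against 25599 ± 4332 in all intestinal cells and at most 122 ± 69.2 in any other group. Epcam, an epithelial adhesion protein, averaged 965 ± 84.1 in the intestinal G sort and 861 ± 109 in all intestinal cells. The 17 B and plasma cell genes summed to between 38037 ± 18813 and 61953 ± 33654 TPM in the splenic sorts. S100a8, a calcium-binding protein abundant in neutrophils and monocytes, averaged 33827 ± 2499 in the marrow G sort and 33803 ± 3617 in the marrow M sort. In the intestinal sorts S100a8 averaged 73.1 ± 107 (G), 6.08 ± 3.5 (M) and 21.9 ± 20.4 (combined).

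**Figure D1:**
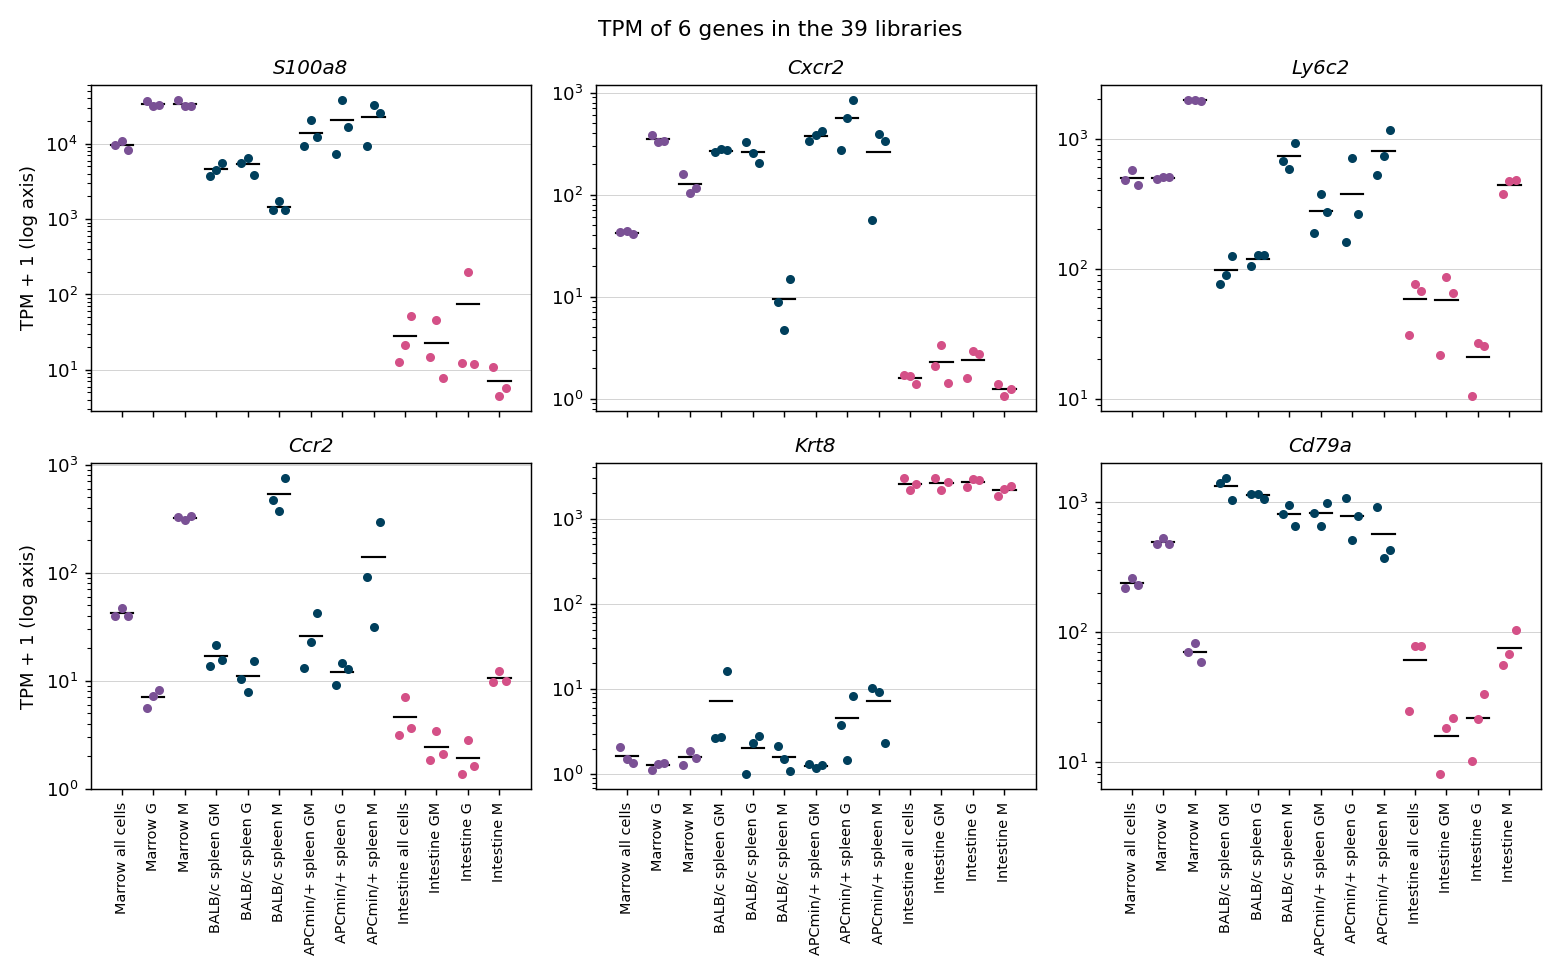
TPM on a log10 axis (after adding 1) of chosen marker genes in the 39 libraries, 1 point per library, with the group means as bars. S100a8 stands near 33827 in the marrow G sort and near 73.1 in the intestinal G sort, and Krt8 stands near 2710.1 in the intestinal G sort.

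The first comparison asked how G and M sorts of newborn marrow differed. Monocyte genes were among those that differed. Ccr2, the receptor that draws monocytes out of marrow, was 6.00 ± 1.34 TPM in the G sort and 323 ± 13.8 in the M sort, a log2 fold change of -5.55 ± 0.49 (adjusted p = 3.34e-10). Fn1, which encodes fibronectin, was 25.2 ± 5.58 against 1046 ± 45.5 (-5.34 ± 0.67). Klf4, a transcription factor of monocytes, was 3.53 ± 0.764 against 94.2 ± 6.63, and S100a4 was 12.8 ± 0.631 against 432 ± 27.0. Ly6c2, which encodes the Ly6C surface antigen and has close relatives that share reads, was 500.4 ± 8.61 against 1976 ± 21.9 (-1.98 ± 0.45, adjusted p = 9.3e-04).

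Of the 20 monocyte genes, 16 were lower and 1 higher in the marrow G sort, also when adjusted over the list alone (median log2 fold change -2.37). Its camera test gave adjusted p = 1.16e-12, and adjusted p = 0.287 with an estimated correlation. The primary granule genes, made at the promyelocyte stage, were lower in 6 of 7 members and higher in 1 (adjusted p = 9.16e-05, and adjusted p = 0.273 with an estimated correlation). Among them Mpo, which encodes myeloperoxidase, was 102 ± 40.1 against 798 ± 139, Prtn3 fell by 3.62 on the log2 scale and Elane, neutrophil elastase, fell by 3.32. Of 16 mature granulocyte genes, 9 were higher in the G sort, 9 also when adjusted over the list alone (adjusted p = 0.0186, and adjusted p = 0.741 with an estimated correlation). The list summed to 121226 ± 6174 TPM in the G sort and 103161 ± 10399 in the M sort, with overlapping libraries. Secondary and tertiary granule genes summed to less in the G sort, at 42413 ± 1910 against 53469 ± 3277, without overlap. Retnlg, a resistin-like protein of neutrophils, was 7142 ± 477 against 1685 ± 441 (2.11 ± 0.61, adjusted p = 0.00815), and Clec4d, a C-type lectin receptor, was 273 ± 26.4 against 65.9 ± 15.4. Cxcr2, the chemokine receptor of neutrophils, was 349.7 ± 31.9 against 125 ± 28.1 (1.49 ± 0.47, adjusted p = 0.0143), and without M library 2 its call was lost (1.37, adjusted p = 0.058). S100a8 showed a log2 fold change of 0.00 ± 0.73, which turned to -0.06 without G library 1 and to -0.04 without M library 2 or M library 3.

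Genes of other lineages were also higher in the marrow G sort. Of the 17 B and plasma cell genes, 12 were higher and 0 lower (adjusted p = 2.31e-07, and adjusted p = 0.441 with an estimated correlation). Vpreb1, part of the surrogate light chain of pre-B cells, was 579 ± 45.3 against 57.6 ± 10.4, Igll1, its partner, was 760.4 ± 34.5 against 78.4 ± 13.8, and Dntt, the terminal transferase of early lymphocytes, was 129.8 ± 18.1 against 11 ± 2.65. Stromal and endothelial genes were higher in 10 of 16 members (adjusted p = 5.7e-06, and adjusted p = 0.535 with an estimated correlation), with Sparc at 99.1 ± 31.2 against 13.1 ± 4.70 and Col1a1, a collagen chain, at 135 ± 44.2 against 23.3 ± 11. Cxcl12, a chemokine of marrow stroma, was 93.5 ± 31.5 against 5.78 ± 2.15, and the protease gene Ctsk was 99.98 ± 4.53 against 2.97 ± 1.34 (4.73 ± 0.20, adjusted p = 2.97e-17). Among genes tied to suppression, Arg2, an arginase, rose by 2.12 and Wfdc17 fell by 2.71 on the log2 scale. By the limma test over 18466 genes, 1886 genes differed at an adjusted p under 0.05 and at least a 2-fold change, 1272 higher and 614 lower in the G sort.

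In the spleen of BALB/c immune-deficient mice neutrophil and monocyte genes separated the sorts. Cxcr2 was 262 ± 61.2 TPM in the G sort and 8.44 ± 5.06 in the M sort (4.92 ± 0.47, adjusted p = 7.62e-09). Mmp9, a gelatinase of neutrophil granules, was 254 ± 32.4 against 14.2 ± 4.57, the interleukin-36 gene Il1f9 was 90.4 ± 14.2 against 3.63 ± 2.98, and Il1b, which encodes interleukin-1 beta, was 732 ± 171 against 101 ± 35.1. Ly6g, the neutrophil antigen of the Ly6 family, was 112 ± 39.3 against 17.3 ± 2.80 (2.58 ± 0.52, adjusted p = 4.8e-04). In the other direction, F13a1, a clotting factor chain made by monocytes, was 1.46 ± 0.223 against 159 ± 16.9 (-6.02 ± 0.49, adjusted p = 4.06e-10), Ccr2 was 10.1 ± 3.65 against 529 ± 199, and Cx3cr1, the fractalkine receptor, was 2.39 ± 0.467 against 105 ± 10.8.

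Of 16 mature granulocyte genes, 13 were higher in the BALB/c G sort, 14 when adjusted over the list alone (median 2.68, adjusted p = 2.13e-15, and adjusted p = 0.273 with an estimated correlation). Of the 20 monocyte genes, 12 were lower, 13 when adjusted over the list alone (median -1.35, adjusted p = 1.06e-09, and adjusted p = 0.405 with an estimated correlation). The secondary and tertiary granule genes were higher in 5 of 14 members, 7 when adjusted over the list alone (adjusted p = 3.1e-04, and adjusted p = 0.588 with an estimated correlation). Elane and Prtn3, of the primary granules, fell by 3.64 and by 3.24. Dendritic cell genes were lower in 7 of 13 members (adjusted p = 1.3e-04, and adjusted p = 0.43 with an estimated correlation), with Clec10a at 3.05 ± 0.220 against 20.0 ± 2.85 and Siglech, of plasmacytoid cells, at 9.38 ± 2.73 against 35.0 ± 8.04. T and NK cell genes were lower in 8 of 17 members (adjusted p = 3.4e-04, and adjusted p = 0.584 with an estimated correlation), among them Trac, the T cell receptor alpha constant region, at 20.5 ± 7.29 against 81.4 ± 38.0. Interferon response genes were lower in 7 of 23 members (adjusted p = 0.00163, and adjusted p = 0.626 with an estimated correlation). S100a8 was 5323 ± 1337 against 1468 ± 249, which did not pass in the fit of 39 libraries (1.84 ± 0.73, adjusted p = 0.0833) and passed in the fit of these 6 libraries alone (adjusted p = 0.00678). The test called 913 genes, 315 higher and 598 lower in the G sort. With each library rescaled by its median ratio the share of called genes that were higher moved from 34.5% to 45.7%.

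In APCmin/+ spleen the sorts differed in monocyte and cell cycle genes, among others. Ccr2 was 11.2 ± 2.74 TPM in the G sort and 139 ± 139.7 in the M sort (-2.98 ± 0.49, adjusted p = 1.0e-04). Fn1 was 6.48 ± 1.70 against 163 ± 163 (-3.83 ± 0.67), F13a1 was 4.09 ± 2.36 against 83.2 ± 78.9, and Ccl9, a chemokine of myeloid cells, was 8.62 ± 2.49 against 111 ± 105. Of 22 cell cycle genes, 17 were lower in the G sort, also when adjusted over the list alone (median -1.45, adjusted p = 9.38e-14, and adjusted p = 0.421 with an estimated correlation). Ccnb1, a mitotic cyclin, was 14.8 ± 5.91 against 51.1 ± 24.6, and Plk1, a mitotic kinase, was 9.95 ± 2.91 against 34.8 ± 14.9. The mitochondrial transcript mt-Nd3 was 1469.8 ± 150.2 against 481 ± 75.8 (1.62 ± 0.23, adjusted p = 2.69e-05).

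The M libraries of APCmin/+ spleen varied. Ccr2 was 89.9, 30.2 and 296 TPM in M libraries 1, 2 and 3, and Cxcr2 was 55.6, 391 and 339 in the same libraries. Of 20 monocyte genes, 10 were lower in the G sort (adjusted p = 3.98e-06, and adjusted p = 0.533 with an estimated correlation). Of 16 mature granulocyte genes, 6 were higher, 8 when adjusted over the list alone (adjusted p = 3.89e-05, and adjusted p = 0.554 with an estimated correlation). The list summed to no more in the G sort, at 60118 ± 42530.3 TPM against 60820.2 ± 32799.8 and lower in 2 of 3 numbered pairs, and secondary and tertiary granule genes summed to 20705 ± 18197 against 33242 ± 14114. These calls hung on single libraries: Cxcr2, at 565 ± 288 against 262 ± 181 with overlapping libraries, had a log2 fold change of 1.38, and its call was lost without G library 2 (1.31), G library 3 (1.02) or M library 1 (0.49). Il1b, at 942 ± 611 against 358 ± 235 and also overlapping, had 1.54 and lost its call without G library 3 (1.05) or M library 1 (0.77). The test called 594 genes, 107 higher and 487 lower in the G sort. The 107 became 220 without G library 1, 172 without G library 2, 55 without G library 3, 162 without M library 2 and 186 without M library 3, and the 487 became 318 without G library 3. After rescaling by median ratios the share higher moved from 18% to 45.7%. A limma fit of these 6 libraries alone called 0 genes, with 428 at an unadjusted p under 0.05, and 0 also with replicate number as a block. Leaving out G library 3 gave 373 calls and leaving out G library 1 gave 939.

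The intestinal G and M sorts differed in lymphoid and inflammatory genes, nearly all higher in the M sort. Ly6c2 was 20.0 ± 9.13 TPM in the G sort and 440.1 ± 54.9 in the M sort (-4.51 ± 0.45, adjusted p = 2.63e-07). Jchain, the joining chain of secreted antibodies, was 382 ± 142 against 4948 ± 474 (-3.77 ± 0.51, adjusted p = 1.39e-05), and Mzb1, an endoplasmic reticulum protein of plasma cells, was 9.38 ± 4.67 against 90.8 ± 14.3. The B and plasma cell genes summed to 8109 ± 3282 TPM in the G sort and 112451 ± 18989 in the M sort. Of the 17 members, 8 were lower in the G sort (mean log2 fold change -1.43, adjusted p = 9.76e-13, and adjusted p = 0.273 with an estimated correlation). Their constant-region genes Igkc (-3.97) and Igha (-3.84) belong to families whose members share reads.

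Inflammatory cytokine and chemokine genes were lower in 9 of 25 members in the intestinal G sort, 11 when adjusted over the list alone (median -0.77, adjusted p = 6.86e-18, and adjusted p = 0.09 with an estimated correlation). Cxcl10, which attracts T cells and is not a member of this list, was 3.48 ± 0.679 against 18.1 ± 1.50 TPM. Il1b was 30.2 ± 11.1 against 109 ± 5.62 (-1.87 ± 0.48, adjusted p = 0.0133), a call lost without G library 2 (-1.73, adjusted p = 0.0683). Of the 22 suppression genes, 5 were lower, 6 when adjusted over the list alone (adjusted p = 4.47e-08, and adjusted p = 0.272 with an estimated correlation), though the list summed to more in the G sort (837 ± 14.7 against 806 ± 17.7 TPM, without overlap). Cd274, which encodes the checkpoint ligand PD-L1, was 3.62 ± 1.17 against 15.1 ± 4.29, Arg1, arginase 1, was 1.48 ± 0.710 against 7.32 ± 1.41, and Ptgs2, cyclooxygenase 2, was 4.21 ± 2.05 against 12.4 ± 2.47. Dendritic cell genes were lower in 8 of 13 members, 9 when adjusted over the list alone (median -1.10, adjusted p = 2.72e-16, and adjusted p = 0.09 with an estimated correlation), including Itgax, the integrin CD11c, at 9.06 ± 3.66 against 26.2 ± 12.3. Monocyte genes were lower in 6 of 20, 8 when adjusted over the list alone (adjusted p = 2.4e-12, and adjusted p = 0.303 with an estimated correlation), with Ccr2 at 0.943 ± 0.788 against 9.67 ± 1.41. T and NK cell genes were lower in 5 of 17, 9 when adjusted over the list alone (adjusted p = 2.26e-12, and adjusted p = 0.273 with an estimated correlation).

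The granulocyte lists did not pass in intestine (adjusted p = 0.114 for primary granules, 0.681 for secondary and tertiary granules and 0.661 for mature granulocytes). The granule lists had 1 of 7 and 1 of 14 members lower in the G sort, and 2 of 16 mature granulocyte genes were higher when adjusted over the list alone. S100a8 was 73.1 ± 107 against 6.08 ± 3.5 TPM, which did not pass (2.24 ± 0.73, adjusted p = 0.0651) and passed with replicate number as a block (adjusted p = 0.0381). It also passed without G library 1 (2.89) or G library 3 (2.92), and without G library 2 the log2 fold change was 0.90. Lyz1, the Paneth cell lysozyme, was 2377 ± 538 against 1153 ± 364 (1.07 ± 0.28), a call lost without G library 2 (0.99), G library 3 (0.95) or M library 1 (0.78), and after rescaling (0.86). The 23 epithelial genes had 1 member higher in the G sort, and the list did not pass. The test called 523 genes, 13 higher and 510 lower in the G sort, against a median of all genes of 0.14 that rescaling moved to -0.01. The 13 became 54 without G library 1, 31 without M library 3, 8 without G library 3 and 4 without M library 1. A fit of these 6 libraries alone called 66, 2 higher and 64 lower, with Ly6c2, Jchain and Cxcl10 among them and not Mzb1, Cd274, Arg1, Ptgs2, Il1b, Ccr2, Itgax, Lyz1, Igkc or Igha, and 261 with replicate number as a block.

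Across sites, 20 genes were higher in the M sort in all 4 comparisons, where independent lists would share 0.0145, and 0 were higher in the G sort in all 4. These comparisons have no library in common. The 20 included Ccr2, S100a4, Ly6c2, the lectin receptor Cd209a, the galectin Lgals1, the natural killer granule gene Nkg7, the checkpoint receptor Havcr2 and the membrane-spanning Ms4a6b, Ms4a6c and Ms4a6d. Marrow and both spleens shared 40 genes higher in G (0.126 for independent lists) and 122 higher in M (0.524). Across 18466 genes, which are not independent replicates, the G against M fold changes of marrow correlated with those of BALB/c spleen (r = 0.46) and of APCmin/+ spleen (r = 0.442). Those of intestine gave r = -0.046 with marrow, r = 0.074 with BALB/c spleen and r = -0.142 with APCmin/+ spleen, and marrow and intestine shared 67 genes higher in M (17 for independent lists) and 0 higher in G (0.895). The 20 shared genes became 0 when each site was fitted alone, since APCmin/+ spleen then had 0 calls, 13 without the low-expression filter, 31 with a pseudocount of 0.1, and 33 without APCmin/+ spleen M library 2.

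**Figure D2:**
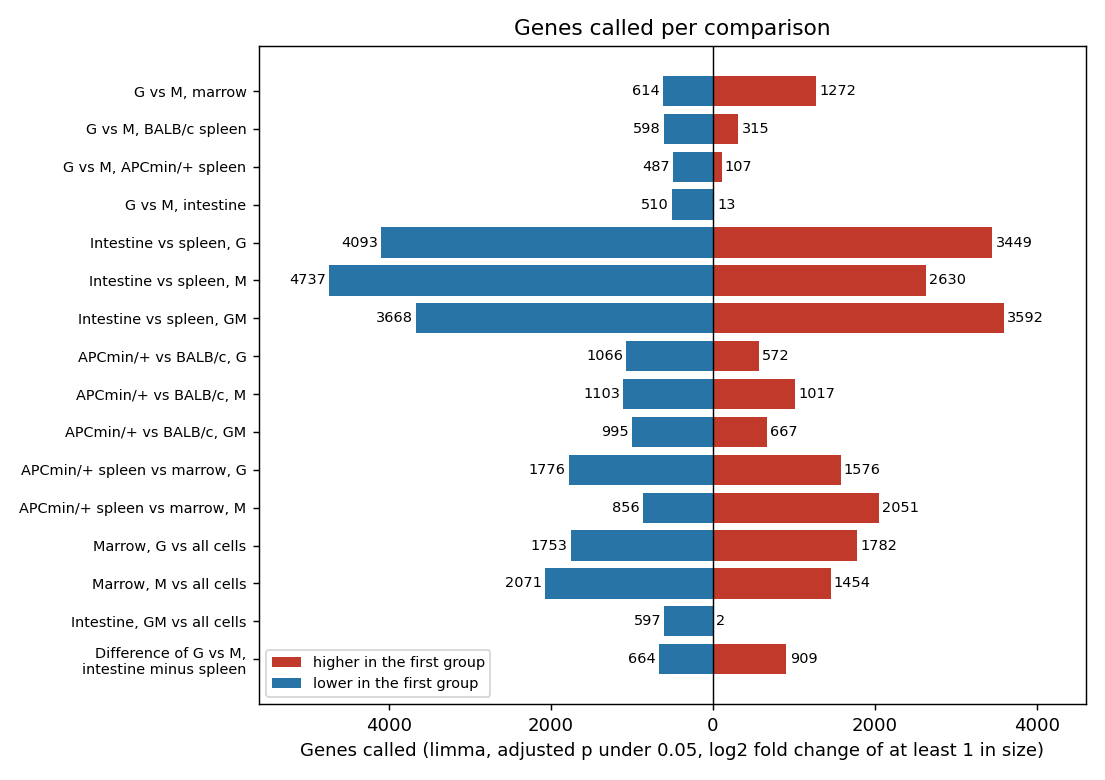
Number of genes called (horizontal axis) in each comparison (vertical axis), split by direction. The intestine against spleen comparisons call the most, with 7542 for the G sort, and the intestinal G against M comparison calls 523.

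Intestine and spleen of APCmin/+ mice were compared for each sort to see how the same labelled population differed between tissues. Epithelial genes were higher in the intestinal G sort and granulocyte genes in the splenic one. Krt8, an epithelial keratin, was 2710.1 ± 315 TPM against 3.53 ± 3.5 (9.55 ± 0.55, adjusted p = 8.9e-16), Apoa1, an apolipoprotein of enterocytes, was 3663 ± 1037 against 4.56 ± 4.63, and Fabp6, an ileal bile acid binding protein, was 7679 ± 3545 against 7.69 ± 6.24. S100a8 was 73.1 ± 107 against 20767 ± 16028 (-9.07 ± 0.73, adjusted p = 2.64e-12), Cxcr2 was 1.42 ± 0.720 against 565 ± 288, and Itgam, the integrin CD11b by which such cells are known, was 8.33 ± 2.55 against 411 ± 211. Cd274 was 3.62 ± 1.17 against 36.2 ± 11.6, and Il1b was 30.2 ± 11.1 against 942 ± 611.

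All 23 epithelial genes were higher in the intestinal sort for G, M and combined cells alike (medians 8.23, 7.77 and 8.69). Their camera adjusted p values were 3.4e-15, 1.99e-19 and 2.95e-15, and adjusted p = 0.273 for each with an estimated correlation. All 14 secondary and tertiary granule genes were lower for the 3 sorts (medians -6.54, -7.10 and -6.43), with adjusted p = 7.9e-06, 1.24e-05 and 3.67e-06, and adjusted p = 0.533, 0.535 and 0.504 with an estimated correlation. Mature granulocyte genes were lower in 15, 16 and 16 of 16 members. All 6 genes of the NADPH oxidase, which makes the oxidative burst, were lower (medians -5.18, -4.10 and -5.41), with adjusted p = 2.3e-04, 0.00137 and 1.3e-04, and adjusted p = 0.43, 0.495 and 0.422 with an estimated correlation. Wnt target genes were higher in 11, 10 and 11 of 15 members and lower in 3, 4 and 2 (adjusted p = 0.00126, 4.1e-04 and 8.3e-04, and adjusted p = 0.588, 0.582 and 0.584 with an estimated correlation). Their sums went the other way, at 332 ± 98.4 against 406 ± 129 TPM in G, 228 ± 65.1 against 379 ± 88.8 in M and 386 ± 145 against 397 ± 80.2 in combined sorts, without overlap only in M. Axin2, a direct Wnt target, was 52.3 ± 11.3 against 1.33 ± 0.093 TPM in G, 35.3 ± 8.52 against 2.90 ± 0.721 in M and 53.9 ± 13.1 against 1.14 ± 0.252 in combined sorts. Lgr5, a marker of intestinal stem cells, was 19.6 ± 4.76 against 0.19 ± 0.104 in G sorts. Oxidative phosphorylation genes were higher in 18, 7 and 17 of 20 members (adjusted p = 1.16e-10, 5.35e-09 and 1.81e-09, and adjusted p = 0.402, 0.43 and 0.421 with an estimated correlation).

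Splenic sorts held more erythroid transcripts, and splenic G and combined sorts more B cell transcripts. B and plasma cell genes were lower in the intestine in 14, 10 and 14 of 17 members, and 3 were higher in the M sort. The list test passed for G and combined sorts (adjusted p = 1.4e-04 and 2.47e-05, and adjusted p = 0.582 and 0.535 with an estimated correlation) and not for M sorts (adjusted p = 0.159, and 0.0166 after rescaling), where the list summed to 112451 TPM in intestine against 38037 in spleen. Ighm was 78.8 ± 39.7 against 11662 ± 4564 TPM in G sorts. Erythroid genes were lower in 12, 12 and 10 of 12 members and higher in 1 for combined sorts (adjusted p = 2.8e-04, 1.9e-04 and 0.00318, and adjusted p = 0.584, 0.582 and 0.638 with an estimated correlation). Major histocompatibility class II genes were lower in 10, 9 and 10 of 10 members, and their test passed for G and combined sorts (adjusted p = 0.00121 and 4.63e-05, and adjusted p = 0.584 and 0.495 with an estimated correlation). For M sorts it gave adjusted p = 0.0746, and 0.0324 after rescaling. Cell cycle genes went apart: 7 of 22 were higher in intestinal G sorts with no pass of the list (adjusted p = 0.215), and 17 of 22 were lower in intestinal M sorts (adjusted p = 0.0184, and adjusted p = 0.837 with an estimated correlation). Mki67, a marker of cycling cells, was 30.1 ± 9.30 against 106 ± 48.1 in M sorts (-1.74, and -1.10 after rescaling).

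Mediator genes went both ways between the intestinal and the splenic M sort. Of 25 inflammatory genes 9 were higher and 4 lower in intestine (adjusted p = 0.0432, adjusted p = 0.689 with an estimated correlation, and adjusted p = 0.0807 after rescaling), while the list summed to 625 ± 74.5 TPM against 1243 ± 440.0 in spleen. Of 22 suppression genes 9 were higher and 9 lower (adjusted p = 0.219), with sums of 806 ± 17.7 against 1181 ± 363. Il1b was 109 ± 5.62 against 358 ± 235 with overlapping libraries (-1.38 ± 0.48, adjusted p = 0.0108), a call lost without spleen M library 2 (-1.09) or 3 (-0.90), after rescaling (-0.73) and in the fit of the 6 libraries alone (adjusted p = 0.114). Cd274 was 15.1 ± 4.29 against 24.9 ± 7.46 and did not pass (-0.67 ± 0.24). Arg1 was 7.32 ± 1.41 TPM against 0.143 ± 0.183 (2.86 ± 0.30, and 5.19 with a pseudocount of 0.1), Nos2, the inducible nitric oxide synthase, was 17.5 ± 16.1 against 0.163 ± 0.147 (3.66 ± 0.57, and 5.83 with a pseudocount of 0.1), and Ptgs2 was 12.4 ± 2.47 against 1.02 ± 0.399. Cxcl2, which attracts neutrophils, was 22.0 ± 6.62 against 0.533 ± 0.106, and Fosb, an immediate early gene that tissue digestion also induces, was 202 ± 35.8 against 2.21 ± 1.01. Ccr2 was 9.67 ± 1.41 against 139 ± 139.7, while Ly6c2 was 440.1 ± 54.9 against 806 ± 323 and did not pass (-0.80 ± 0.45, adjusted p = 0.109). In combined sorts, Muc2, the gel-forming mucin of goblet cells, was 2394 ± 75.7 against 0.593 ± 0.071 (10.55 ± 0.42, adjusted p = 7.51e-20), and Ly6g was 34.4 ± 6.79 against 149 ± 94.5. The test called 7542 genes for G (3449 higher in intestine, 4093 lower), 7367 for M (2630 and 4737) and 7260 for combined sorts (3592 and 3668). The medians of all genes were -0.16, -0.43 and -0.15, and rescaling moved the share higher in M sorts from 35.7% to 60.8%. Across 18466 genes the G and the M fold changes correlated with r = 0.93.

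Whether the G against M difference itself changed between the tissues of APCmin/+ mice was tested as an interaction, in which a negative value means a lower G to M ratio in intestine than in spleen. The intestinal sorts held epithelial genes at 31205 (G) and 28602 (M) TPM. Their B and plasma cell genes summed to 8109 (G) and 112451 (M) TPM. Which cells carried the differences was not tested. Jchain (-4.10 ± 0.72, adjusted p = 2.5e-04) and Mzb1 (-3.58 ± 0.60) led the plasma cell genes. Il1b had -3.41 ± 0.67 (adjusted p = 7.1e-04), with 30.2 against 109 TPM in intestine and 942 against 358 in spleen. Cd274 had -2.32 ± 0.34 (adjusted p = 5.34e-05), Ptgs2 had -2.28 ± 0.44 and Arg1 had -1.79 ± 0.42, and Ly6c2 had -3.21 ± 0.63. In the splenic M sort Arg1 lay below a TPM of 1, near the floor of log2(TPM + 1). The value for Arg1 therefore says little about its G to M ratio in spleen. The opposite sign was seen for Nupr1, a stress-response gene, with 3.40 ± 0.60, for Fcnb, a ficolin of myeloid cells, with 3.26 ± 0.54, and for Ccl9 with 2.83 ± 0.65.

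Of the 22 cell cycle genes, 21 had a higher G to M ratio in intestine (median 1.82, adjusted p = 3.41e-11, and adjusted p = 0.455 with an estimated correlation). B and plasma cell genes were lower in 8 of 17 (adjusted p = 1.87e-11, and adjusted p = 0.273 with an estimated correlation). Inflammatory genes were lower in 6 of 25, 7 when adjusted over the list alone (adjusted p = 7.42e-09, and adjusted p = 0.273 with an estimated correlation), and suppression genes in 6 of 22 (adjusted p = 1.33e-06, and adjusted p = 0.273 with an estimated correlation). The test called 1573 genes, 909 higher and 664 lower, of which 1463 had G against M fold changes of opposite sign in both tissues and 4 were called in both in opposite directions. The 909 became 1422 without spleen G library 1 and 602 without intestinal M library 1. The median of all genes was 0.23, and rescaling moved the share higher from 57.8% to 21.3%. A fit of the 12 libraries alone called 247 and lost the calls of Il1b, Ly6c2, Nupr1 and Ccl9, and with replicate number as a block it called 1623, these 4 included.

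The splenic sorts of APCmin/+ and BALB/c immune-deficient mice were compared next, a comparison in which strain, genotype and health go together and cannot be told apart. Cycling and erythroid genes were higher in APCmin/+ spleen. Ccna2, a cyclin of DNA replication, was 68.4 ± 35.9 TPM against 10.5 ± 1.89 in M sorts (2.49 ± 0.29, adjusted p = 7.29e-08), and Birc5, survivin, was 45.2 ± 26.1 against 6.97 ± 0.635 in combined sorts. Klf1, the erythroid transcription factor, was 20.8 ± 9.66 against 2.73 ± 1.92 in G sorts and 55.8 ± 47.8 against 3.55 ± 0.787 in M sorts. Cell cycle genes were higher in 11 (G), 19 (M) and 14 (combined) of 22 members (medians 1.02, 2.00 and 1.80), with adjusted p = 4.89e-10, 1.32e-19 and 1.16e-19, and adjusted p = 0.495, 0.273 and 0.273 with an estimated correlation. Erythroid genes were higher in 8, 9 and 11 of 12 members, 9, 10 and 12 when adjusted over the list alone (adjusted p = 1.58e-07, 9.26e-08 and 1.52e-11, and adjusted p = 0.43, 0.421 and 0.273 with an estimated correlation).

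The M sorts also differed in granulocyte genes. S100a8 was 22479 ± 11977 TPM in the APCmin/+ M sort against 1468 ± 249 in the BALB/c M sort (3.76 ± 0.73, adjusted p = 1.7e-04). Ltf, the secondary granule protein lactoferrin, was 7122 ± 3470.1 against 351 ± 107, Cxcr2 was 262 ± 181 against 8.44 ± 5.06, and Ly6g was 236 ± 169 against 17.3 ± 2.80. Secondary and tertiary granule genes were higher in 8 (G), 13 (M) and 9 (combined) of 14 members, 9, 13 and 13 when adjusted over the list alone (adjusted p = 3.65e-07, 1.56e-12 and 2.97e-08, and adjusted p = 0.453, 0.273 and 0.43 with an estimated correlation). Mature granulocyte genes were higher in 14 of 16 members in M sorts, 16 when adjusted over the list alone (adjusted p = 6.22e-14, and adjusted p = 0.273 with an estimated correlation). Monocyte genes were lower in 12 of 20 in M sorts (adjusted p = 0.00149, and adjusted p = 0.65 with an estimated correlation), with Ccr2 at 139 ± 139.7 against 529 ± 199, a call lost in the fit of the 6 libraries alone (adjusted p = 0.114). The macrophage list was lower in 8, 2 and 10 of 16 members and passed for combined sorts, with 13 when adjusted over the list alone (adjusted p = 0.00207, and adjusted p = 0.656 with an estimated correlation). The combined sorts of APCmin/+ spleen were split, with sums of the list of 637, 509.9 and 4845 TPM in libraries 1, 2 and 3 against 4234 to 4291 in BALB/c, so the lower values rest on libraries 1 and 2, and library 3, the only one of them with Xist, lay above all of BALB/c. For G sorts it gave adjusted p = 0.0919, and 0.0177 after rescaling. Spic, a transcription factor of red pulp macrophages, was 60.0 ± 26.6 against 380.5 ± 50.5 in G sorts.

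Several of the largest splenic differences lay in single genes of families that vary between strains. Trim12a was 203 ± 29.6 TPM against 1.27 ± 0.180 in G sorts (6.49 ± 0.18, adjusted p = 2.84e-22) and Gvin1 was 84.7 ± 16.2 against BALB/c libraries listed at 0. Ly6c1 was 2.72 ± 1.66 against 675 ± 171 in M sorts, and Ifi202b was listed at 0 in the APCmin/+ M sorts against 117 ± 40.5. These belong to gene families with shared reads. Ccl24, an eosinophil chemokine, was 3.34 ± 1.26 against 80.1 ± 7.01 in G sorts and 5.67 ± 4.12 against 101 ± 20.2 in M sorts. The test called 1638 genes for G (572 higher, 1066 lower in APCmin/+), 2120 for M (1017 and 1103) and 1662 for combined sorts (667 and 995), with medians of all genes of -0.15, -0.14 and -0.12. The 1103 became 713 without APCmin/+ M library 2. Rescaling moved the share higher from 34.9% to 48.4% for G and from 48.0% to 59.6% for M, and fits of the 6 libraries alone called 1047 for M and 994 for combined sorts.

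Sorts of APCmin/+ spleen were set against those of newborn C57BL/6 marrow, which differ in tissue, age and genotype together and in mitochondrial share (8.58% against 2.72% in G and 4.40% against 2.16% in M sorts). Sex-linked transcripts differed too. The Y-linked Ddx3y ran from 6.42 to 34.74 TPM in the marrow G and M libraries and was at most 0.04 in the splenic ones. Antigen presentation and interferon genes were higher in spleen. H2-Eb1, a class II chain, was 1089 ± 400.3 TPM against 12.2 ± 0.709 in G sorts (6.30 ± 0.32, adjusted p = 4.27e-16), and H2-Aa was 1367 ± 564 against 13.4 ± 0.742 in M sorts. Cd274 was 36.2 ± 11.6 against 3.44 ± 0.685 in G sorts and 24.9 ± 7.46 against 3.86 ± 0.914 in M sorts, and Il1b was 942 ± 611 against 130.2 ± 21 in G sorts and 358 ± 235 against 38.3 ± 9.72 in M sorts. Class II genes were higher in 10 (G) and 9 (M) of 10 members (adjusted p = 8.2e-13 and 4.69e-10, and adjusted p = 0.273 for both with an estimated correlation). Interferon response genes were higher in 19 and 17 of 23 members (adjusted p = 1.42e-13 and 8.34e-10, and adjusted p = 0.273 and 0.366 with an estimated correlation).

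Cell cycle genes were lower in spleen than in marrow in 21 (G) and 14 (M) of 22 members (adjusted p = 4.83e-10 and 1.02e-09, and adjusted p = 0.495 and 0.504 with an estimated correlation). Mpo was 9.21 ± 9.63 against 102 ± 40.1 in G sorts and 57.3 ± 74.3 against 798 ± 139 in M sorts. The precursor B cell gene Igll1 was 0.043 ± 0.051 against 760.4 ± 34.5 in G sorts, while Cr2, the complement receptor of mature B cells, was 490.2 ± 148 against 1.2 ± 0.763 and Jchain was 1506 ± 633 against 3.08 ± 1.61. B and plasma cell genes were higher in 11 (G) and 15 (M) of 17 members and lower in 3 and 2 (adjusted p = 4.3e-04 and 2.09e-07, and adjusted p = 0.584 and 0.44 with an estimated correlation). T and NK cell genes were higher in 15 and 16 of 17 (adjusted p = 3.38e-09 and 5.1e-12, and adjusted p = 0.405 and 0.273 with an estimated correlation). Stfa1, a stefin A cysteine protease inhibitor whose copies share reads, was 15 ± 6.06 against 24058 ± 1345 in G sorts. Ccr2 was 139 ± 139.7 against 323 ± 13.8 in M sorts (-1.78), a call lost without spleen M library 2 (-0.98) and in the fit of the 6 libraries alone (adjusted p = 0.157). The test called 3352 genes for G (1576 higher, 1776 lower in spleen) and 2907 for M (2051 and 856).

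Sorted marrow was set against all marrow cells to see what the gates enriched. Xist was 204.65 TPM in all-cell library 1 against 0.99 and 0.22 in G and M libraries 1. The samples thus do not all come from the same set of animals, and differences between animals cannot be told apart from those of the gates. The G sort held more Cxcr2 (349.7 ± 31.9 against 41.6 ± 1.51 TPM, 3.04 ± 0.47, adjusted p = 2.9e-06), Ly6g (279.7 ± 16.8 against 41.4 ± 8.22) and Itgam (753 ± 44.7 against 131 ± 11.8). The M sort held more Ccr2 (323 ± 13.8 against 41.1 ± 4.19, 2.95 ± 0.49), Fn1 (1046 ± 45.5 against 86.9 ± 7.24) and Ly6c2 (1976 ± 21.9 against 497 ± 68.3). Hbb-bs, a beta globin whose copies share reads, was 614 ± 141 in G and 245 ± 48.5 in M against 26486 ± 8611. Erythroid genes were lower in 12 of 12 members in both sorts (adjusted p = 2.04e-06 and 4.47e-08, and adjusted p = 0.453 and 0.405 with an estimated correlation). In the G sort 15 of 16 mature granulocyte genes were higher (adjusted p = 9.15e-06, and adjusted p = 0.509 with an estimated correlation), and in the M sort 18 of 20 monocyte genes were (adjusted p = 1.25e-07, and adjusted p = 0.453 with an estimated correlation). Granulocyte sums were not raised in the G sort alone. Mature granulocyte genes summed to 121226 (G) and 103161 (M) TPM against 30823 in all cells. Secondary and tertiary granule genes summed to 42413 (G) and 53469 (M) against 14920. Primary granule genes summed to less in the sorts, at 828 (G) and 2592 (M) against 3540. Dissociation and immediate early genes were higher in 12 and 10 of 18 members and lower in 1 in the M sort (adjusted p = 1.61e-05 and 1.18e-05, and adjusted p = 0.535 and 0.533 with an estimated correlation). Fos was 251 ± 58.6 in G and 335 ± 89.7 in M against 9.11 ± 1.36. The test called 3535 genes for G (1782 higher, 1753 lower) and 3525 for M (1454 and 2071, median of all genes -0.10). S100a8 passed in both sorts (1.82 ± 0.73, adjusted p = 0.0385 and 0.0389) and lost each call without any 1 of the libraries compared and without the low-expression filter (adjusted p = 0.0701 and 0.0719).

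Nearly all genes that set the combined intestinal sort apart from all intestinal cells were lower in the sort, those of lymphoid, stromal and myeloid lists alike. T and NK cell genes were lower in 13 of 17 members, 14 when adjusted over the list alone (median -1.76, adjusted p = 3.99e-27, and adjusted p = 0.09 with an estimated correlation). B and plasma cell genes were lower in 10 of 17, 14 when adjusted over the list alone (adjusted p = 7.56e-18, and adjusted p = 0.272 with an estimated correlation), class II genes in 9 of 10 (adjusted p = 1.9e-18, and adjusted p = 0.145 with an estimated correlation), and stromal and endothelial genes in 10 of 16, 12 when adjusted over the list alone (adjusted p = 7.47e-14, and adjusted p = 0.273 with an estimated correlation). Monocyte genes were lower in 4 of 20, 5 when adjusted over the list alone (adjusted p = 0.00272, and adjusted p = 0.662 with an estimated correlation), and macrophage genes in 1 of 16, 7 when adjusted over the list alone (adjusted p = 8.2e-04, and adjusted p = 0.638 with an estimated correlation). Dendritic cell genes were lower in 6 of 13, 7 when adjusted over the list alone (adjusted p = 9.39e-15, and adjusted p = 0.09 with an estimated correlation), and NADPH oxidase genes in 4 of 6 (adjusted p = 1.04e-10, and adjusted p = 0.21 with an estimated correlation). Mcpt1, a mucosal mast cell protease, was 4.51 ± 1.88 TPM against 48.0 ± 20.0 (-3.14 ± 0.33, adjusted p = 1.68e-06), and Ccl21a, a lymphatic chemokine, was 4.64 ± 2.36 against 49.7 ± 26.2. Of the 23 epithelial genes 0 were called by limma, with a median log2 fold change of -0.03. Their list lay above the other genes by camera (adjusted p = 0.0261, adjusted p = 0.812 with an estimated correlation, and adjusted p = 0.101 after rescaling). Ly6g was 34.4 ± 6.79 against 21 ± 6.07 with overlap between libraries and did not pass (0.71 ± 0.52, adjusted p = 0.727), nor did S100a8 at 21.9 ± 20.4 against 27.3 ± 20.3 (-0.45 ± 0.73, adjusted p = 0.987), which turned to 0.10 without library 3 of all cells and to 0.12 without combined library 3. The test called 599 genes, 2 higher and 597 lower. Without library 2 of all intestinal cells it called 364, 361 of them lower, and the 2 became 6 without combined library 2 and 1 without combined library 1. The mitochondrial share was 15.5% ± 0.748 in the sort against 10.9% ± 1.66 in all cells, without overlap between libraries. A limma fit of these 6 libraries called 5, with neither Mcpt1 nor Ccl21a, and 0 with replicate number as a block.

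Combined sorts hold G and M cells per the labels, so a gene outside both single sorts was counted where the combined sort passed against each in the same direction. In BALB/c spleen limma called 0 such genes (48 at an unadjusted p under 0.05 in both tests), and in APCmin/+ spleen 0 (67). The 0 became 5 without BALB/c combined library 1, 3 without G library 1 and 1 without combined library 2 or 3 or M library 1 or 3. In APCmin/+ spleen it became 130 without combined library 3, 7 without combined library 1, and 1 without combined library 2 or G library 1. In intestine 315 genes lay outside, 254 above and 61 below both, and a fit of the 9 sorted intestinal libraries alone called 217, 212 above and 5 below. Car1, a carbonic anhydrase of colonic epithelium and red cells, averaged 1113 ± 364 TPM in the combined sort and lay 9.35 above the nearer of the G and M sorts on the log2 scale, Saa1, an acute phase protein, lay 7.05 above and Tgm3, a transglutaminase, 6.60 above. Gzma (-2.72), Gzmb (-2.22) and Ccl5 (-2.25), genes of cytotoxic lymphocytes, lay below, and these 3 calls were lost in that fit (adjusted p = 0.116 for Gzma, 0.145 for Gzmb and 0.166 for Ccl5). As a mixture of the mean G and M profiles, the combined sort was placed at a G share of RNA of 1.000 with SD 0 in BALB/c spleen (883 genes, at the upper bound), 0.783 ± 0.067 in APCmin/+ spleen (579 genes) and 0.877 ± 0.068 in intestine (477 genes). In APCmin/+ mice combined libraries 1 and 2 held the Y-linked Ddx3y and the single sorts held Xist, so there the share places a sort between those of other animals and does not measure their mixing.

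**Figure D3:**
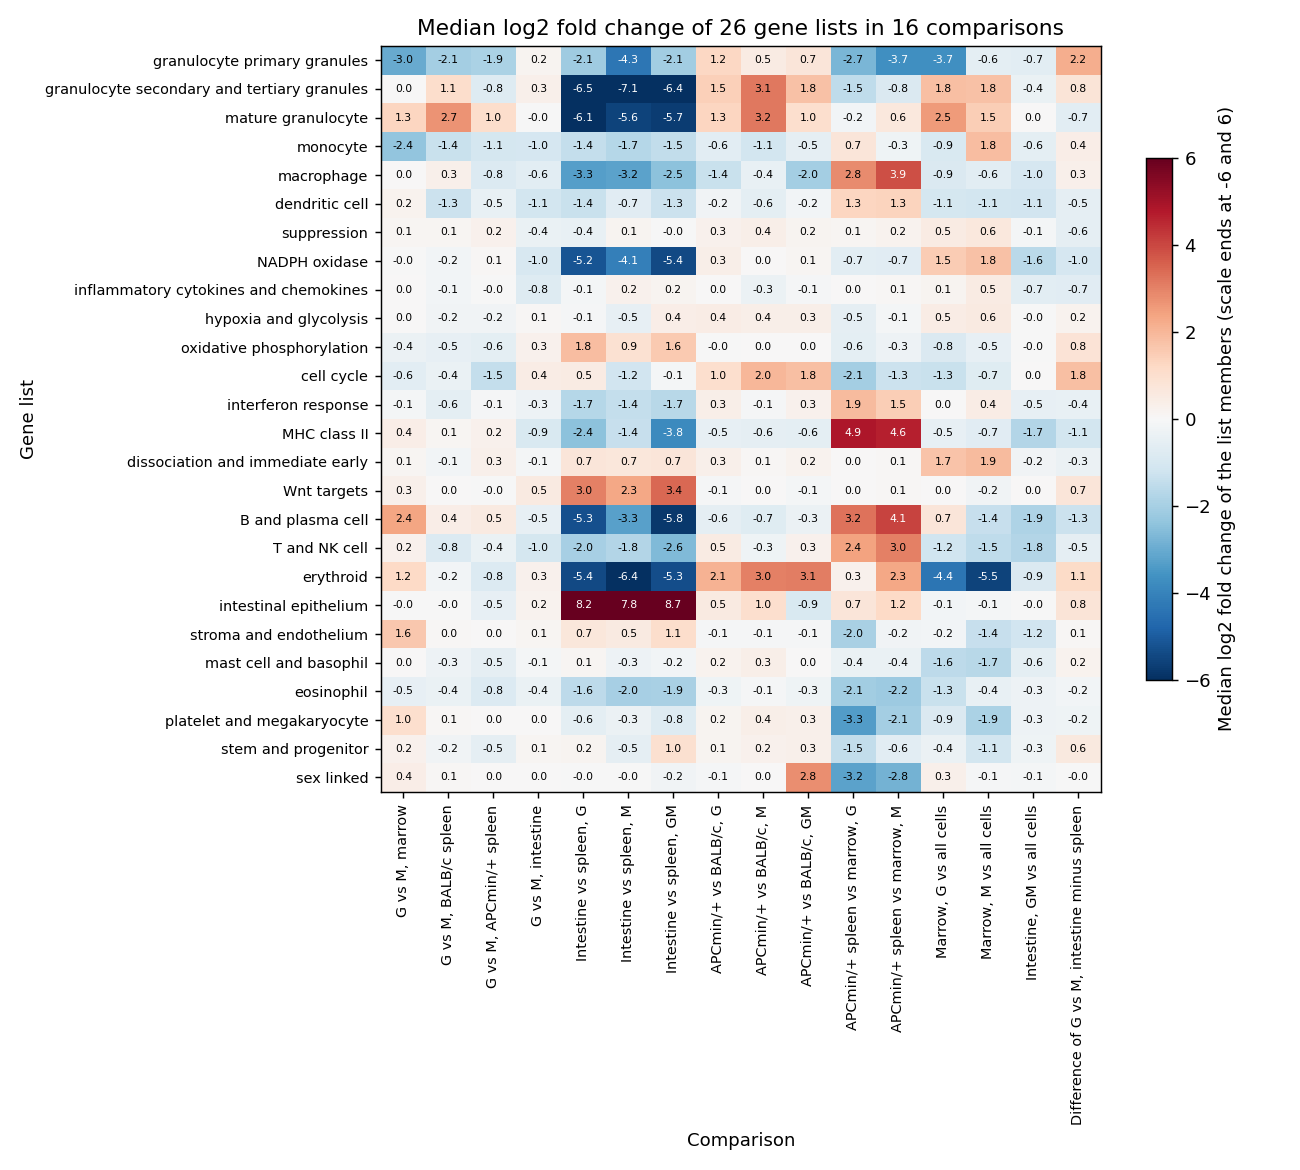
Median log2 fold change (colour) of the 26 gene lists (vertical axis) in the 16 comparisons (horizontal axis). The epithelial list has medians of 8.23, 7.77 and 8.69 in the intestine against spleen comparisons, and the cell cycle list has a median of -1.45 in the G against M comparison of APCmin/+ spleen.

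In GENCODE M21 on GRCm38 (mm10), Ccr2 lies on chromosome 9 from 124101950 to 124113557 (+), Cxcr2 on chromosome 1 from 74153989 to 74161246 (+), Ly6c2 on chromosome 15 from 75108158 to 75111970 (-), S100a8 on chromosome 3 from 90668978 to 90670035 (+), Il1b on chromosome 2 from 129364570 to 129371139 (-), and Jchain on chromosome 5 from 88519809 to 88527891 (-). All are annotated as protein coding.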

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

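The interaction, the B cell test of the splenic sorts and the colonic epithelium test of the combined intestinal sort were set before their results were seen, and the other tests in this part, those of the splits included, were chosen after. Groups of 3 libraries were not tested for single samples far from the others.

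The G against M contrast of APCmin/+ mice differed between intestine and spleen by a test of the difference itself. The interaction called 1573 genes. Since the intestinal sorts also held epithelial and plasma cell transcripts, it compares sorted samples, and which cells carried the differences was not tested. A negative value, a lower G to M ratio in intestine, was found for Jchain (-4.10), Mzb1 (-3.58), Fam214a (-3.53), Il1b (-3.41), Lax1 (-3.31), Ly6c2 (-3.21), Cd274 (-2.32), Ptgs2 (-2.28) and Arg1 (-1.79). Arg1 lay near the floor in the splenic M sort, so its ratio in spleen is uncertain. A positive value was found for Nupr1 (3.40), Fcnb (3.26), Tppp3 (3.19), Fn1 (3.07) and Ccl9 (2.83). Fn1 lost its call without spleen M library 3 (2.21) or intestine G library 2 (2.77). In a fit of the 12 libraries alone the calls of Il1b (adjusted p = 0.0675), Ly6c2 (0.0573), Nupr1 (0.073), Tppp3 (0.12), Fn1 (0.113) and Ccl9 (0.105) were lost, and with replicate number as a block, which called 1623 genes, all 6 were called. The splits of the samples give 1 of 100 as large, the real one, with 1312 genes in the highest other, a share under 0.05 when pairs are ignored. The replicate numbers pair these samples. Of the 99 others, 16 part all 6 pairs and reach at most 530 genes, and 83 part fewer pairs and reach 1312. Those 16 are too few for a share under 0.05, so chance is not excluded among splits that part the pairs.

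Epithelial transcripts in the intestinal sorts are the first pattern weighed. The 23 genes had a median ratio of 1.014 between the sorts and all intestinal cells (0.722 to 3.012), and Fabp6 reached 7679 TPM and Krt8 2710.1 in the G sort, where a sort for myeloid cells would remove epithelial cells. Sorted and all-cell libraries exchanged are argued against, since the lowest sum of epithelial genes in an all-cell library was 21576 TPM, against a mean of 28308 in the sorts. A tissue programme in cells that are all myeloid is argued against by the NADPH oxidase list, with a median of -5.18 against the splenic G sort. Epithelial cells or their RNA in the sorted samples may explain the pattern and stay open, as does a difference between the tissues in which cells pass the gate.

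B cell transcripts in the splenic sorts are the next. Over the 18 libraries the log2 ratios of 9 mature B cell genes to Cd79a had a median SD of 0.1747, and 7 granulocyte genes one of 1.846. Granulocyte genes differ between the sorts pooled here, so their ratios vary whatever the source of the B cell transcripts. The contrast therefore shows that the B cell genes move together and does not decide where they come from. Ighm reached 11662 TPM in the APCmin/+ G sort. B cells or their RNA in the sorted samples may explain this, a sort on myeloid antigens would remove them, and the difference between kinds of mice and tissues was not tested as a cause.

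The last pattern is the 315 genes of the combined intestinal sort outside both single sorts. An effect of that sort itself is argued against by a median of 0.0125 against all intestinal cells for the 254 genes above both. Colonic epithelium in these samples may explain the pattern, with a median of 3.72 over 11 colon genes (11 higher) and -0.76 over 12 small intestinal genes (0 higher), whose sums were 1304.9 against 266.1 (G) and 228.8 (M) TPM for colon and 3626.7 against 6467.3 and 6689 for small intestine. Male animals stay open, since only combined library 3 holds Xist (a median of 0.24 above the other 2, with Ddx3y, over the 254 genes), as do segments of gut, which the labels do not give.

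For comparisons of 3 against 3 the splits number 10, and a share under 0.05 cannot be reached with them. In each the real split alone was as large (1 of 10). For G against M the real and the highest other counts were 1886 and 1 (marrow), 913 and 3 (BALB/c spleen), 594 and 448 (APCmin/+ spleen) and 523 and 74 (intestine). Intestine against spleen gave 7542 and 28 (G), 7367 and 252 (M) and 7260 and 9 (combined). APCmin/+ against BALB/c spleen gave 1638 and 1 (G), 2120 and 297 (M) and 1662 and 267 (combined), and against marrow 3352 and 2 (G) and 2907 and 5 (M). Sorts against all cells gave 3535 and 10 (marrow G), 3525 and 1 (marrow M) and 599 and 362 (intestine). Where the numbers pair samples, the highest of the 3 other splits that part all 3 pairs was 12 for APCmin/+ spleen, 0 for intestine and 2 for combined against all intestinal cells, and those that part fewer pairs gave the higher counts above.

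Over 100 splits each, the shared genes (20 against 0) had 1 as large. Other splits of marrow called at most 1 gene, and those of BALB/c spleen at most 3. A split that mixes the marrow sorts can thus share hardly any gene, whatever the other sites hold. The low counts were therefore largely set in advance, so they cannot decide whether the sharing across sites is chance, which is not excluded. The list tests had 3 as large (210 against 221), a share under 0.05 for the total number of passes. These splits shuffled all libraries over all groups without regard to pairs, and 99 of the others pass at least 1 list. They therefore do not exclude chance for any single list. The 210 passes rest on the preset correlation, and with an estimated one 0 of the 416 list tests by camera pass. For genes of the combined sort outside both others, limma gave 0 in BALB/c spleen (48 at an unadjusted p under 0.05 in both tests) and 0 in APCmin/+ spleen (67). All 100 splits reach a count of 0, so they say nothing about chance there, and the highest others were 7 and 462. The 462 set combined library 3 and M libraries 1 and 3 against the other 6, which points to a structure of the samples whose cause was not tested. In intestine 5 were as large, with 519 in the highest other against 315. Of the 4 others as large, 2 kept the 3 combined libraries together and 2 put the 3 M libraries in their place. Each thus set a whole real group against the rest, so this count cannot decide on chance, which is not excluded. The 15 others that part all 6 numbered pairs reached at most 6 genes, and the 4 as large were among the 84 that part fewer.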

How the results depend on the processing

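Of the alternatives below, the block within the groups compared, the fit of only these groups with a block, and leaving out the APCmin/+ spleen libraries numbered 2 were added after seeing the data. The last were chosen because they hold the highest S100a8 of their groups. Where a count moved, the cause was not tested unless given.

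Of 263 results for single genes, 188 had the same call and direction under every alternative run. Over 3481 values, 210 lost their call, 6 gained one and 5 changed sign. The sign changed only for S100a8, from 0.00 in marrow G against M to -0.06 without G library 1 and to -0.04 without M library 2 or M library 3, and from -0.45 in combined against all intestinal cells to 0.10 without all-cell library 3 and 0.12 without combined library 3. Over all libraries left out in turn the 2 values ran from -0.06 to 0.09 and from -1.15 to 0.12. The cause was not tested.

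With a pseudocount of 0.1, which widens the fold changes of low values, G against M calls became 3134 in marrow and 967 in APCmin/+ spleen. APCmin/+ against BALB/c spleen gave 2559 (G), 3292 (M) and 2697 (combined), APCmin/+ spleen against marrow M 4553, and combined against all intestinal cells 974. Genes outside in BALB/c spleen became 1 and the shared genes 31. Without the filter the shared genes were 13.

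Without the fold minimum, which can only add genes, G against M calls were 5693 (marrow), 3322 (BALB/c spleen), 3851 (APCmin/+ spleen) and 1184 (intestine). Intestine against spleen gave 12925 (G), 13419 (M) and 12630 (combined), APCmin/+ against BALB/c spleen 5731, 7132 and 5034, and APCmin/+ spleen against marrow 8829 (G) and 7943 (M). Sorted against all cells gave 9357 (marrow G), 9334 (marrow M) and 948 (intestine). The interaction gave 4676, genes outside 1 (BALB/c) and 852 (intestine), and the shared genes were 39.

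Fitting only the groups compared, with the spread taken from their own libraries, gave 0 limma calls for G against M in APCmin/+ spleen (428 at an unadjusted p under 0.05) and 66 in intestine. It gave 1047 (M) and 994 (combined) for APCmin/+ against BALB/c spleen, 5 for combined against all intestinal cells, 247 for the interaction and 0 shared genes. With a block added to that fit, the counts were 0 for APCmin/+ spleen, 261 for intestine, 0 for combined against all intestinal cells and 1623 for the interaction. Without a block, fits of as few libraries gave 1938 G against M calls in marrow and 877 in BALB/c spleen. Fewer samples alone therefore do not account for the 0 and the 66. The fit of all libraries assumes a common spread per gene for every group.

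Replicate number as a block in the fit of all libraries gave 608 G against M calls in APCmin/+ spleen, 544 in intestine, 615 for combined against all intestinal cells and 1614 for the interaction, the results whose numbers pair samples. S100a8 in intestinal G against M gained its call with the block (2.24, adjusted p = 0.0381), and the block changed no other call of these results. Where samples share only a number, the block gave 1904 in marrow, 929 in BALB/c spleen, and 7546, 7382 and 7274 for intestine against spleen (G, M, combined), with every marrow G and BALB/c G library correlating best with the M library of its own number, which did not hold for every library between intestine and spleen G or combined sorts. Of the list tests 213 passed with the block, 204 of them among the 210, and none of those that changed was in a comparison whose numbers pair samples. These counts include APCmin/+ spleen against BALB/c spleen and against marrow. The blocks were set within each kind of mouse, so there they give no blocked form of the main test.

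Without the APCmin/+ spleen libraries numbered 2, genes outside in APCmin/+ spleen became 1 and the shared genes 31. With an estimated correlation 0 of 416 list tests by camera passed, against 210 with the preset one. After rescaling 208 passed, 191 of them among the 210, and no total of called genes moved by more than 1.5 times. Directions moved further: the interaction went from 909 higher and 664 lower to 320 and 1183, and G against M in APCmin/+ spleen from 107 and 487 to 235 and 279. The G share of combined sorts became 0.996 in BALB/c spleen and 0.953 in APCmin/+ spleen with no upper TPM limit, and 0.984, 0.894 and 0.961 (intestine) with an error on the log2 scale.

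Leaving out 1 library at a time gave 373 (without G library 3) to 939 (without G library 1) for G against M in APCmin/+ spleen, 364 (without all-cell library 2) to 874 (without all-cell library 1) for combined against all intestinal cells, and 14 to 33 (without APCmin/+ spleen M library 2) shared genes. Genes outside ran from 0 to 5 (without combined library 1) in BALB/c spleen and from 0 to 130 (without combined library 3) in APCmin/+ spleen. The G share ran from 0.984 to 1.000 in BALB/c spleen and from 0.656 (without G library 1) to 0.905 (without G library 3) in APCmin/+ spleen. Every other total of called genes stayed within 1.5 times its value when 1 library was left out. Directions moved further: higher in G against M went from 13 to between 4 (without M library 1) and 54 (without G library 1) in intestine and from 107 to between 55 and 220 in APCmin/+ spleen, and higher in the interaction from 909 to between 602 and 1422. TPM keeps no depth, so what depth limits could not be assessed.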

Other observations

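The tests here were planned, and the lists were chosen for this part after their values were seen. Some list tests that the report does not describe also passed. Platelet and megakaryocyte genes were lower in APCmin/+ spleen than in newborn marrow in 7 of 7 members for both sorts, with medians of -3.35 (G) and -2.05 (M), adjusted p = 2.12e-07 and 2.27e-08, and adjusted p = 0.273 for both with an estimated correlation. Stem and progenitor genes were lower in 8 (G) and 5 (M) of 11 members, with medians of -1.48 and -0.63 and adjusted p = 2.53e-05 and 4.4e-04, and adjusted p = 0.273 and 0.402 with an estimated correlation. Stromal and endothelial genes were lower in spleen than in marrow G sorts in 10 of 16 members (median -1.97, adjusted p = 1.8e-04, and 0.588 with an estimated correlation).

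Within marrow, mast cell and basophil genes were lower in the sorts than in all cells in 7 (G) and 9 (M) of 11 members, with medians of -1.59 and -1.66, adjusted p = 2.9e-04 and 4.9e-04, and adjusted p = 0.453 and 0.462 with an estimated correlation. Platelet and megakaryocyte genes were lower in the M sort in 7 of 7 (median -1.88, adjusted p = 7.1e-04, and 0.453 with an estimated correlation). Hypoxia and glycolysis genes were higher in APCmin/+ than in BALB/c spleen in 4 (G), 3 (M) and 2 (combined) of 21 members, with medians of 0.45, 0.36 and 0.34, adjusted p = 1.27e-07, 6.05e-05 and 3.5e-04, and adjusted p = 0.366, 0.482 and 0.535 with an estimated correlation. Oxidative phosphorylation genes were lower as a list in G than in M sorts by camera with 0 of 20 called by limma, at medians of -0.35 (marrow), -0.48 (BALB/c spleen) and -0.61 (APCmin/+ spleen), adjusted p = 1.09e-06, 4.69e-10 and 1.56e-13, and adjusted p = 0.504, 0.405 and 0.273 with an estimated correlation. In intestine the list was higher in G sorts by camera, also with 0 of 20 called (median 0.27, adjusted p = 2.0e-04, adjusted p = 0.588 with an estimated correlation, and adjusted p = 0.0849 after rescaling).

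The sex of the animals is not in the labels. Xist, expressed from the inactive X chromosome of females, and Ddx3y, on the Y chromosome, gave these readings. All 3 libraries of all marrow cells held both transcripts, as did numbers 2 and 3 of the marrow G and M sorts, while number 1 of each held Ddx3y with Xist at 0.99 (G) and 0.22 (M) TPM. All BALB/c libraries and all G and M sorts of APCmin/+ spleen and intestine held Xist. The combined sort of APCmin/+ spleen, the combined intestinal sort and all intestinal cells held Ddx3y in numbers 1 and 2 and Xist in number 3. In APCmin/+ mice the combined sorts therefore include animals other than those of the single sorts.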
